A study of Saccharomyces cerevisiae with 58 samples.

How the data were processed

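The series holds 58 Agilent arrays in 29 groups of 2, each hybridised with a chromatin immunoprecipitate (ChIP) in one dye and its input DNA in the other. Scanner files were available for 55 arrays. Per the file headers, the authors extracted them with Agilent Feature Extraction and a linear dye normalization, so the processed signals used here are background-subtracted, dye-normalized intensities. The deposited value table, per its own description and values, holds log2 ratios of ChIP to input centred near 0. The array labelled bur1as/ctk1Δ Sth1 SC replicate 1, one bur1as/ctk1Δ Rpb3 SM array and one STH1-TET Rpb3 SM doxycycline array have values in that table only and were used in the value-table alternative.

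For each of the 41775 non-control spots the log2 ratio of the processed ChIP signal to the processed input signal was taken, outlier spots named by the extraction software were set to missing, and each array was centred on the median of its 41480 nuclear spots. Spots were assigned to genes by the annotation columns of the array itself, which name the gene and the offset from its start, because no genome build is named in the files and positions on one chromosome lie off the current reference. No coordinates are given for that reason. A gene's value was the mean of its coding-sequence (CDS) probes. Of 5438 genes with a CDS probe, 4976 had at least 2 and were tested, after 13 engineered or marker genes (such as CTK1, GCN5, STH1 and URA3) were left out. Upstream values were means over probes within 500 bp 5' of the start and outside every CDS, for 5167 genes. Some divergent pairs share upstream probes.

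Classes by position were set by gene order. Probes of 248 intergenic intervals that hold a tRNA gene by gene order (1541 of 10913 intergenic probes) stood in for windows around tRNA genes, and genes of at least 1500 bp were found from the offset of their last probe.

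The direction of each ratio came from the dye labels. On 52 arrays the labels and the value table had the same sign. On 3 arrays (kin28as/bur2Δ Sth1 SM replicates 1 and 2, and STH1-TET Rpb3 SM doxycycline replicate 1) they were opposite, and the direction of the value table was used. With the label direction these arrays had median correlations of -0.676, -0.610 and -0.641 with the other arrays of their antibody, and with the direction used all 26 arrays at odd slide positions of that scanner have ChIP in green and all 27 at even positions in red. With the label direction each of the 3 was negatively correlated with every array of its antibody that was not turned (highest r -0.169, -0.236 and -0.217). These values argue against the label direction. No file states which direction is right, so counts and main values that rest on these arrays are also given with the label dyes.

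Genes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the data.table package, version 1.17.8. There was one fit per antibody, with a term per group and a covariate for the dye that carried the ChIP. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Residual degrees of freedom were 9 for Sth1, 12 for Rpb3 and 2 for H3, with 4.94, 3.41 and 4.19 added by the prior. A mutant was compared with wild type (WT) as the mean of its differences in both media, and the SC difference, the SM difference and their contrast were fitted beside it. Groups with 1 array borrow the spread of the other groups. A joint fit of Sth1 and Rpb3 arrays tested whether the Sth1 change differed from the Rpb3 change of the same strain. Extraction and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

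Up to 8 genes per direction are named for each comparison, namely those with the largest change among the called genes whose change had the same sign in each dye orientation, with a standard name. For each list the 2 members with the smallest p can be named too. The tests, the gene lists, this rule and the alternatives below were fixed before the data were examined, except where stated. The 16 lists are Gcn4 targets of amino acid synthesis, cytosolic ribosomal proteins, ribosome biogenesis, glycolysis and fermentation, Hsf1 chaperones, the general stress response (Msn2/4), methionine and sulfur, purine and one-carbon, respiration, phosphate response, galactose genes, histone genes, meiosis and sporulation, a-cell markers, alpha-cell markers and RSC subunits. They were written from general knowledge of yeast genes. Lists were tested against all other genes with camera (preset inter-gene correlation 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks only whether a list's genes move one way, were the alternatives. Lists with fewer than 3 tested members got no list test. No list called with camera differed in sign between its mean, its median and the direction of the test.

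Values per array were the mean Sth1 or Rpb3 of the 200 genes with the highest Rpb3 in the STH1-TET SC arrays without doxycycline minus that of all other genes, the mean over tRNA intervals minus the array median, upstream minus CDS, and the last minus the first of 3 equal parts of the highly transcribed genes of at least 1500 bp (19 genes for the mutants, 15 for doxycycline). Mutants were compared with WT by exact two-sided permutation tests over all splits of the arrays, adjusted over the 4 mutants, and WT upstream against CDS by an exact two-sided sign-flip test.

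Alternatives were normexp background correction (offset 50), arrays scaled to one spread, no dye term, the replicate number as a block, the median of probes, at least 1 CDS probe, bright probes only, only the arrays of the groups compared, the value table, slide as a block, 100 or 500 highest genes, a 250 bp upstream window and each array left out in turn. Another 7 were chosen after seeing the data. These are the label dyes for the 3 arrays, leaving those arrays out, leaving out the bur1as/ctk1Δ array that carries CTK1 DNA, 500 genes for the profile along genes, and the gcn5Δ/esa1ts and kin28as/bur2Δ arrays as control, also without the turned arrays and with the label dyes. The fits were tested on simulated data with 50 genes changed by each of -1, -0.5, 0.5 and 1 at the spread and array numbers of these data. The ctk1Δ Sth1 fit recovered 96%, 80%, 68% and 100% of them with 6 false calls among 178, and the WT SM against SC Rpb3 fit 56%, 24%, 24% and 76% with 9 false calls among 99. The simulated noise was independent between genes and arrays, without slide effects, so these rates need not hold for the real counts.

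The 29 groups lie on 16 slides scanned on 9 days, each group on 1 slide. Groups compared with each other share a slide for WT YPD and SC (both antibodies), for doxycycline within each medium (Rpb3) and in SC (H3), for WT and gcn5Δ/esa1ts Sth1 in SM and for WT and kin28as/bur2Δ Rpb3 in SM. In the other comparisons slide and group cannot be told apart. Dixon's outlier test was not run because no group holds more than 2 arrays. Intensities above background were checked: 41744, 41736 and 41728 of the 41775 probes were above background in the input of every Sth1, Rpb3 and H3 array.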

Results

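The arrays measured 3 ChIP targets in budding yeast. The first was Sth1, the ATPase of the RSC chromatin remodelling complex, through a Myc tag. The others were Rpb3, a subunit of RNA polymerase II, and histone H3. Cells grew in synthetic complete medium (SC), in rich medium (YPD), or in SC with sulfometuron methyl (SM, 0.65 µM for 20 minutes), an inhibitor of branched-chain amino acid synthesis that induces the transcription factor Gcn4. Strains were WT, gcn5Δ/esa1ts (lacking the histone acetyltransferase Gcn5 and with a temperature-sensitive Esa1, another), ctk1Δ (lacking a polymerase II tail kinase), bur1as/ctk1Δ and kin28as/bur2Δ (spelled kina28as/bur2Δ in the labels), which carry kinases that an added inhibitor blocks, and STH1-TET, in which doxycycline represses STH1. The source field of the ctk1Δ arrays gives bur1as/ctk1Δ, without inhibitor, so bur1as/ctk1Δ against ctk1Δ may be inhibitor against none in 1 strain. Each of the 29 groups held 2 arrays and 3 groups had a scanner file for 1 of them, so the number of arrays limits the precision. Values are log2 ChIP/input relative to the array median, so they show shares of the signal and not absolute binding. Replicate arrays correlated across genes at between 0.329 (STH1-TET Rpb3 SC with doxycycline) and 0.965 (STH1-TET Rpb3 SC without it), and genes are not independent replicates.

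Input DNA was read at genes that the strain names say are missing. GCN5 was below -3 (log2 relative to the other arrays of the same dye) on 8 of 8 gcn5Δ/esa1ts arrays (median -7.01) and CTK1 on 8 of 8 ctk1Δ arrays (median -5.56). CTK1 was below -3 on 5 of 6 bur1as/ctk1Δ arrays. The exception was the array labelled bur1as/ctk1Δ Sth1 SC replicate 2, the only Sth1 SC array of that strain with a scanner file, which carried CTK1 at 0.56 and URA3 at 6.60. BUR2 was below -3 on 0 of 8 arrays labelled kin28as/bur2Δ (lowest -0.62, median -0.06), while these arrays lacked ADE2 (median -6.09) and LYS2 (median -5.81). Each of these genes was covered by a few probes, and no test was made. The Rpb3 signal on STH1 in the STH1-TET strain was 3.04 ± 0.77 (SD, n = 2) in SC and 2.62 ± 0.69 (n = 2) in SM without doxycycline. With doxycycline it was -0.05 ± 0.14 (n = 2) in SC and -0.47 on the 1 SM array, against 0.60 in WT SC and -0.01 in WT SM. The drop of -3.02 had an exact two-sided p of 0.0286 over 3 against 4 arrays, which was the smallest possible p, and without any 1 array p was 0.0667 or 0.1. With the label dyes of the 1 SM doxycycline array the drop was -2.71.

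The first question was where RSC lies relative to transcription. In WT SC, Sth1 on cytosolic ribosomal protein genes was 0.91 ± 0.26 (SD, n = 2) above other genes, on glycolysis genes 0.69 ± 0.02 and on respiration genes 0.42 ± 0.02. It was lower than on other genes at galactose genes (-0.42 ± 0.08), which are repressed in glucose. Rpb3 in WT SC followed the same order, with 2.15 ± 0.59 on ribosomal protein genes, 1.75 ± 0.39 on glycolysis genes and -1.09 ± 0.07 on galactose genes. Sth1 and Rpb3 levels correlated across genes in SC (Pearson r = 0.725, Spearman rho = 0.692, 4974 genes), in SM (0.538 and 0.468) and in YPD (0.601 and 0.584). Between arrays with opposite dyes, r was 0.612 and 0.635 in SC, 0.429 and 0.533 in SM, and 0.494 and 0.631 in YPD. Genes are not independent replicates and 2 arrays per medium are too few for a test across arrays. WT Sth1 on the 200 genes of highest Rpb3, relative to other genes, was 1.2 ± 0.12 in SC, 0.71 ± 0.01 in SM and 1.1 ± 0.29 in YPD.

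Over all genes, WT Sth1 upstream probes exceeded CDS probes by 0.15 ± 0.13 (SD, n = 6) and did so on 5 of 6 arrays. The exact two-sided sign-flip p was 0.0625, above the smallest possible of 0.03125, so the difference did not pass the test. The same value was 0.14 ± 0.16 for WT Rpb3 (n = 6) and -0.26 ± 0.06 for H3 in STH1-TET (n = 6). WT Sth1 over intergenic intervals with a tRNA gene, which RNA polymerase III transcribes, was 0.47 ± 0.16 above the array median (n = 4, SC and SM).

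SM was used to induce the amino acid genes through Gcn4. Rpb3 rose in WT on ARG4 (YHR018C, argininosuccinate lyase) by 3.56 ± 0.26 (SE, 2 SM against 2 SC arrays, limma adjusted p = 2.64e-07) and on HIS4 (YCL030C) by 3.18 ± 0.20 (adjusted p = 5.09e-08). ARG1 (YOL058W) rose by 3.34 ± 0.34, and ARG7, RTC2, ARG3 and CPA1 by 3.06 to 3.25. Rpb3 fell on PUS2 (YGL063W, a tRNA pseudouridine synthase; -2.39 ± 0.32, adjusted p = 8.18e-05), NAT4 (YMR069W, -2.17 ± 0.32), CYC3 (YAL039C, -2.06 ± 0.26), LOT5 (-2.01 ± 0.31) and OPI3 (-2.01 ± 0.44). Rpb3 rose on 657 and fell on 627 of 4976 genes. The count of 1284 became 666 without WT SM replicate 1 and 662 without WT SM replicate 2.

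Of the 43 Gcn4 targets, 38 rose, 0 fell and 5 were not called (40 rose adjusted over the list alone), with a mean of 1.66 and a camera adjusted p of 1.11e-29, which held with an estimated correlation (0.0226). HIS1 rose by 2.14 ± 0.12 and UGA3 by 2.08 ± 0.12. Ribosome biogenesis genes fell, 29 of 53 with 24 not called (38 over the list alone), by -0.63 on average (adjusted p = 1.99e-13, or 0.0226 with an estimated correlation). Examples were NSR1 (-1.78 ± 0.25) and MPP10 (-1.30 ± 0.18). Respiration genes fell too, 7 of 19 with 12 not called (mean -0.45, adjusted p = 0.000211, or 0.0226 with an estimated correlation), such as QCR6 (-0.94) and SDH4 (-0.85). For the 101 ribosomal protein genes the mean was -0.47, with 39 lower, 0 higher and 62 not called (45 lower over the list alone; adjusted p = 1.75e-11, but adjusted p = 0.292 with an estimated correlation), and this mean was 0.36 when arrays were scaled to one spread. Glycolysis genes (6 of 17 lower, 8 over the list alone, mean -0.52, adjusted p = 0.00394, but adjusted p = 0.32 with an estimated correlation) likewise had a mean of 0.13 with scaled arrays. The direction of both these lists is therefore not settled.

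The other lists were called with camera only or not at all. Hsf1 chaperones had 9 of 23 lower and 1 higher (mean -0.46; HSC82 -1.40 ± 0.19, SSA2 -1.46 ± 0.24), with adjusted p = 0.241 with an estimated correlation. Galactose genes had 3 of 6 higher (mean 0.52, 0.129 with an estimated correlation), purine genes 7 higher and 1 lower of 15 (mean 0.39, 0.121), methionine genes 5 higher and 1 lower of 19 (mean 0.33, 0.32; STR3 2.31 ± 0.20), meiosis genes 5 higher and 1 lower of 37 (mean 0.26, 0.32), and general stress genes 2 of 24 higher (mean 0.31, 0.383). The 3 a-cell markers were all higher (mean 0.81, 0.129 with an estimated correlation), among them BAR1 (0.97) and STE6 (0.67). RSC subunits had 3 of 15 lower (mean -0.19, camera adjusted p = 0.456), LDB7 (-1.27) and RSC8 (-0.90) among them. None of the 8 phosphate genes was called (mean 0.02, median -0.02, camera direction down, adjusted p = 0.901). Histone genes had 1 tested member, HHO1 (-1.68 ± 0.59), which was -0.845 without WT SC replicate 1, -1.74 and -1.61 without WT SM replicates 1 and 2 (not called in these 3 settings), and -2.51 without WT SC replicate 2. Both alpha-cell markers rose (STE3 by 0.48 and SAG1 by 0.43), without a list test.

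Sth1 in WT was compared between SM and SC to see whether RSC goes to induced genes. Sth1 rose on ARG4 by 1.54 ± 0.16 (SE, 2 against 2 arrays, limma adjusted p = 0.000122), HIS4 by 1.48 ± 0.12 and ARG56 (YER069W) by 1.23 ± 0.09, all genes on which Rpb3 rose. It rose also on VMA1 (YDL185W) by 1.28 ± 0.16. It fell on HTC1 (YPL067C, -1.84 ± 0.26, adjusted p = 0.00124), PUS2 (-1.56 ± 0.31), CCW14 (YLR390W-A, -1.42 ± 0.16) and RPL9A (YGL147C, -1.42 ± 0.27). Sth1 rose on 242 and fell on 336 genes, but with scaled arrays the split was 144 and 79. The count was 42 without WT SM replicate 1, 142 without WT SM replicate 2, 195 without WT SC replicate 1 and 208 without WT SC replicate 2. Of the Gcn4 targets 23 rose, 0 fell and 20 were not called (24 over the list alone; mean 0.56, camera adjusted p = 9.79e-19, but adjusted p = 0.113 with an estimated correlation). The a-cell markers rose, 3 of 3 (mean 0.55, 0.113 with an estimated correlation). Ribosomal protein genes (1 higher, 19 lower, 81 not called, 33 lower and 1 higher over the list alone; mean -0.32, adjusted p = 2.79e-08) lost the call with an estimated correlation (0.624), and their mean was 0.08 with scaled arrays. Glycolysis genes had 5 of 17 lower (mean -0.35, 0.624 with an estimated correlation).

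YPD against SC compared media on shared slides. Rpb3 rose on CHA1 (YCL064C, serine catabolism) by 1.83 ± 0.18 (SE, 2 against 2 arrays, limma adjusted p = 7.51e-05) and on the metal uptake genes FRE1 (YLR214W) by 1.68 ± 0.16 and CTR1 (YPR124W) by 1.29 ± 0.22. It rose on the polyphosphate genes VTC3 (YPL019C) by 1.29 ± 0.20 and VTC4 by 0.96 ± 0.16. It fell on HSP12 (YFL014W, -1.62 ± 0.26), CWP1 (YKL096W, -1.48 ± 0.21), the inositol transporter ITR1 (YDR497C, -1.41 ± 0.11, adjusted p = 9.75e-06) and the osmolyte gene GPD1 (-0.97 ± 0.21). In all 15 genes rose and 31 fell, or 8 and 8 with scaled arrays and 12 and 14 in the value table. The count of 46 became 3 without WT SC replicate 1, 231 without WT SC replicate 2, 11 without YPD replicate 1 and 3 without YPD replicate 2. Camera with an estimated correlation kept 4 lists. Respiration genes had a mean of -0.48 (5 of 19 lower, 10 over the list alone, adjusted p = 0.000173; ATP1 -0.79 ± 0.13) and general stress genes of -0.57 (3 of 24 lower, 10 over the list alone, 0.0217). Phosphate genes had a mean of 0.70 (2 of 8 higher, 5 over the list alone, 0.000998) and purine genes of 0.32 (1 of 15 higher, 4 over the list alone, 0.0126). Ribosomal protein, ribosome biogenesis and meiosis genes had 0 called genes and small means of 0.07, 0.14 and 0.13, which lost the camera call with an estimated correlation (0.737, 0.195 and 0.218). For Sth1, limma called 0 genes, and 894 had an unadjusted p below 0.05. The number of called genes rose from 0 to 888 without YPD replicate 1, 17 without YPD replicate 2 and 6 without WT SC replicate 1. The Sth1 mean of ribosomal protein genes was -0.15 with 0 called (camera adjusted p = 7.41e-07, but adjusted p = 0.721 with an estimated correlation), and that of respiration genes -0.16 (0.652).

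The Gcn4 response to SM was then compared between strains. The Rpb3 response (SM minus SC, Gcn4 targets minus other genes) was 1.66 in WT with 38 genes higher, 1.05 in gcn5Δ/esa1ts (32), 0.99 in ctk1Δ (27), 0.85 in bur1as/ctk1Δ (13) and 1.06 in kin28as/bur2Δ (36). Each passed with an estimated correlation (highest adjusted p 0.0242). The Sth1 response was 0.60 in WT (23 genes), 0.28 in gcn5Δ/esa1ts (6), 0.21 in ctk1Δ (0), 0.08 in bur1as/ctk1Δ (0) and 0.33 in kin28as/bur2Δ (16). With an estimated correlation, adjusted over the strains' responses, the WT response held (0.0242), though not when adjusted over the lists of its comparison (0.113), and the others did not, with 0.0938 in gcn5Δ/esa1ts, 0.163 in ctk1Δ, 0.487 in bur1as/ctk1Δ and 0.124 in kin28as/bur2Δ. The bur1as/ctk1Δ Sth1 value rests on the array labelled SC replicate 2, was 0.01 without SM replicate 1 and was -0.05 in the value table. The kin28as/bur2Δ Sth1 value becomes -0.43 with the label dyes.

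The change of response from WT, as the mean over Gcn4 targets, was tested as a difference. For Rpb3 it lay between -0.76 and -0.55 in the mutants (camera adjusted p between 4.54e-12 and 2.32e-06). For Sth1 it lay between -0.48 and -0.20 (between 7.4e-16 and 1.11e-05). With an estimated correlation 0 of these 8 differences passed, with adjusted p between 0.179 and 0.211. SM and SC arrays of each strain lay on different slides.

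**Figure D1:**
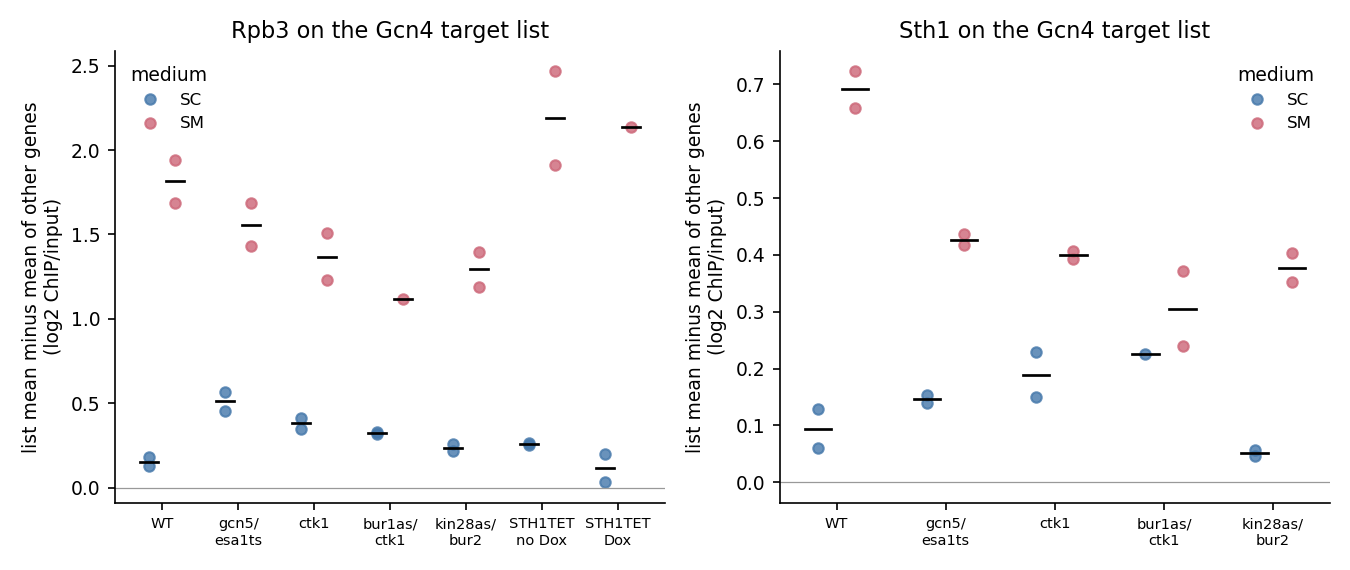
Each point is 1 array and gives the mean log2 ChIP/input of the Gcn4 targets minus that of all other genes in SC or SM for Rpb3 (left) and Sth1 (right), and bars are group means. Sth1 in SM lies at 0.66 and 0.72 on the WT arrays and at 0.44 or less on the mutant arrays, with kin28as/bur2Δ SM drawn in the direction of the value table.

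The gcn5Δ/esa1ts strain was compared with WT to ask whether histone acetyltransferases affect RSC. No temperature is given, so it is unknown whether Esa1 was inactive. Sth1 rose on SED1 (YDR077W, a cell wall protein gene) by 1.3 ± 0.14 (SE, 4 against 4 arrays, limma adjusted p = 0.000105), on the glycolysis genes PGK1 (YCR012W) by 1.23 ± 0.12 and CDC19 (YAL038W) by 1.05 ± 0.09, and on URA2 (YJL130C) by 1.01 ± 0.07. It fell on PET122 (YER153C, -2.01 ± 0.24, adjusted p = 0.000286), ATS1 (YAL020C, -1.77 ± 0.26) and LDB7 (YBL006C, itself an RSC subunit gene, -1.12 ± 0.15). Sth1 rose on 480 and fell on 1008 genes. The SC arrays alone, on different slides, called 1628 genes, the SM arrays alone, on a shared slide, 128, and the difference between media was called for 137. Without WT SM replicate 1 the count was 896, without WT SC replicate 1 958 and without gcn5Δ/esa1ts SC replicate 1 866. Glycolysis genes rose, 13 of 17 with 4 not called (14 over the list alone), by 0.60 on average (camera adjusted p = 5.43e-13, but adjusted p = 0.147 with an estimated correlation). Hsf1 chaperones (6 higher, 2 lower, 15 not called; mean 0.11; HSP60 0.75 ± 0.09) and meiosis genes (9 higher, 2 lower, 26 not called; mean 0.09) were called with camera only (both 0.341). Ribosome biogenesis genes had a negative mean (-0.05) while the camera direction was up. Ribosomal protein genes averaged -0.10, or 0.02 with scaled arrays.

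Rpb3 in gcn5Δ/esa1ts rose on the heat shock genes HSP26 (YBR072W) by 2.13 ± 0.13 (SE, 4 against 4 arrays, adjusted p = 1.06e-07) and SSA1 (YAL005C) by 1.5 ± 0.17, on the trehalose gene TSL1 (YML100W) by 1.62 ± 0.17 and on URA2 by 1.82 ± 0.11. It fell on AIM20 (YIL158W, -1.47 ± 0.15), on the linker histone gene HHO1 (YPL127C, -1.34 ± 0.41, not called when any of 7 of the 8 arrays was left out, with -0.924 without WT SC replicate 1) and on the a-cell genes STE2 (YFL026W, -1.15 ± 0.14) and BAR1 (YIL015W, -1.14 ± 0.13). It rose on 490 and fell on 637 genes, with 1225 called in SC, 263 in SM and 585 for the difference between media. The count became 732, 582 and 709 without WT SM replicate 1, WT SM replicate 2 and WT SC replicate 1, and 683, 592, 726 and 650 without gcn5Δ/esa1ts SM replicates 1 and 2 and SC replicates 1 and 2. Hsf1 chaperones had 14 higher and 1 lower of 23 (16 and 1 over the list alone, mean 0.67, camera adjusted p = 4.98e-10, but adjusted p = 0.0687 with an estimated correlation). Stress genes had 13 of 24 higher (16 over the list alone, mean 0.58, 0.0765; GLC3 0.96 ± 0.13), glycolysis genes 11 of 17 (15 over the list alone, mean 0.63, 0.157; ENO1 1.47 ± 0.22) and respiration genes 6 of 19 (mean 0.20, 0.0789). Ribosomal protein genes had 23 of 101 lower (26 over the list alone, mean -0.23, 0.652), methionine genes 5 lower and 1 higher of 19 (mean -0.31, 0.296) and a-cell markers 3 of 3 lower (mean -1.04, 0.0687). The Gcn4 targets had a mean of 0.02 (-0.24 with scaled arrays) and a median of -0.00109. In the joint fit, the Sth1 change lay above the Rpb3 change on 176 genes and below it on 336. It lay below on Hsf1 chaperones (11 of 23, mean -0.57, 0.0683 with an estimated correlation) and stress genes (11 of 24, mean -0.56, 0.0688), and above on a-cell markers (2 of 3, mean 0.655, 0.0683) and ribosomal protein genes (12 of 101, mean 0.132, 0.518). Camera alone also called respiration genes (3 of 19 below, mean -0.327, 0.118), Gcn4 targets (1 above and 3 below of 43, mean -0.201, or 0.0381 with scaled arrays, 0.607), and, above, ribosome biogenesis (mean 0.102, 0.363), methionine (0.176, 0.363) and meiosis genes (0.135, 0.243). The count of 512 ranged from 246 without WT Rpb3 SM replicate 2 to 340 without gcn5Δ/esa1ts Rpb3 SM replicate 1 among the arrays that moved it by more than 1.5 times.

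The ctk1Δ strain tested a kinase of the polymerase II tail. Sth1 fell on PET122 by -2.02 ± 0.24 (SE, 4 against 4 arrays, limma adjusted p = 0.000737), on RRN5 (YLR141W, a polymerase I factor gene) by -1.95 ± 0.29, on RSO55 (YLR281C) by -1.88 ± 0.28, on WHI5 (YOR083W) by -1.54 ± 0.23 and on PHO4 (YFR034C) by -1.51 ± 0.16. It rose on FLO11 (YIR019C, a flocculin gene) by 0.88 ± 0.15 (adjusted p = 0.00149), FLO5 by 0.60 ± 0.13 and PKH2 by 0.57 ± 0.08. Sth1 rose on 702 and fell on 816 genes, with 1821 called in SC alone, 746 in SM alone and 995 for the difference between media. Leaving out an array gave 980 (WT SM replicate 1), 996 (WT SM replicate 2), 698 (ctk1Δ SM replicate 2), 801 (ctk1Δ SC replicate 1) and 898 (ctk1Δ SC replicate 2). On ribosomal protein genes Sth1 fell, 93 of 101 with 8 not called (98 over the list alone), by -0.54 on average (RPL30 -0.98 ± 0.12, RPL22B -0.76 ± 0.09; camera adjusted p = 2.49e-30, but adjusted p = 0.422 with an estimated correlation). Glycolysis genes had 10 of 17 lower (11 over the list alone, mean -0.40, 0.464), respiration genes 5 of 19 (6 over the list alone, mean -0.27, 0.422; ATP17 -0.69 ± 0.08), Hsf1 chaperones 8 of 23 (mean -0.15, 0.464) and Gcn4 targets 12 lower and 3 higher of 43 (mean -0.14, 0.733).

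Rpb3 in ctk1Δ fell on RDS1 (YCR106W, -1.08 ± 0.10, SE, 4 against 4 arrays, adjusted p = 4.58e-05), the NAD synthesis gene BNA1 (YJR025C, -1.02 ± 0.10), HXT1 (-0.99 ± 0.23) and RPL5 (YPL131W, -0.98 ± 0.14), and rose on SNZ1 (YMR096W, vitamin B6 synthesis) by 1.02 ± 0.20 and ATG2 (YNL242W) by 0.74 ± 0.12. It rose on 212 and fell on 386 genes (685 called in SC, 139 in SM, 215 for the difference). The count was 282, 186 and 394 without WT SM replicate 1, WT SM replicate 2 and WT SC replicate 1, and 299, 249, 260 and 188 without ctk1Δ SM replicates 1 and 2 and SC replicates 1 and 2. Respiration genes fell, 9 of 19 with 10 not called (13 over the list alone), by -0.42 on average (ATP1 -0.60 ± 0.09, ATP2 -0.58 ± 0.08), which held with an estimated correlation (0.00217). Ribosomal protein genes had 76 of 101 lower (96 over the list alone, mean -0.61, camera adjusted p = 3.52e-37, but adjusted p = 0.118 with an estimated correlation; RPL2B -0.83 ± 0.10). Glycolysis genes had 7 of 17 lower (12 over the list alone, mean -0.46, 0.394), a-cell markers 3 of 3 (mean -0.57, 0.118), purine genes 3 of 15 (mean -0.23, 0.191) and Gcn4 targets 7 lower and 2 higher of 43 (mean -0.18, 0.784). The joint fit called 6 genes, with the Sth1 change above the Rpb3 change on RDS1 (0.85), AAD3 (0.74), CYC7 (0.72) and TRS120 (0.51) and below it on CTO1 (-0.59) and RGI2 (-0.69). These genes were chosen after their values were seen. Camera put a-cell markers (mean 0.415), respiration (0.142) and ribosome biogenesis genes (0.124) above, with 0 called genes and not with an estimated correlation (0.183, 0.283 and 0.706). The joint count was 10 without WT Rpb3 SC replicate 2, and 3 without WT Sth1 SM or SC replicate 2, WT Rpb3 SM replicate 2, ctk1Δ Sth1 SM replicate 2, either ctk1Δ Sth1 SC array, ctk1Δ Rpb3 SM replicate 2 or either ctk1Δ Rpb3 SC array.

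In bur1as/ctk1Δ with inhibitor, Sth1 fell on RRN5 (-2.23 ± 0.33, SE, 3 against 4 arrays, limma adjusted p = 0.00226), RSO55 (-2.19 ± 0.31), PET122 (-2.08 ± 0.27), YAT1 (YAR035W, -1.74) and PHO4 (-1.67 ± 0.18), and rose on FLO11 (0.75 ± 0.16). It rose on 393 and fell on 502 genes. In SC, where the array labelled replicate 2 stands alone and carries CTK1, limma called 0 genes (887 at an unadjusted p below 0.05), and in SM 818. The difference between media was called for 9 genes, among them CCW14 (1.70), SDH4 (1.2) and HRT3 (0.98), higher in SM, and HIS4 (-1.21), ARG56 (-1.22), RTC2 (-1.34), ECM13 (-0.83) and INA17 (-0.86), lower in SM, all chosen after their values were seen. The count of 895 was 488 without WT SM replicate 1, 473 without WT SM replicate 2, 551 without WT SC replicate 2 and 435 without bur1as/ctk1Δ SM replicate 2. Ribosomal protein genes had 84 of 101 lower (95 over the list alone, mean -0.56, camera adjusted p = 2.95e-35, but adjusted p = 0.351 with an estimated correlation; RPL22B -0.84 ± 0.10, RPS3 -0.71 ± 0.09). Glycolysis genes had 10 of 17 lower (mean -0.36, 0.516), respiration genes 5 of 19 (mean -0.23, 0.516) and Gcn4 targets 9 of 43 (mean -0.16, 0.625).

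Rpb3 in bur1as/ctk1Δ fell on CWP1 (-1.56 ± 0.17, SE, 3 against 4 arrays, adjusted p = 0.000219), RPL9A (-1.16 ± 0.15), BAR1 (-1.16 ± 0.15) and ASC1 (YMR116C, a ribosome component gene, -1.15 ± 0.15), and rose on SER3 (YER081W, 0.76 ± 0.14), RPN4 (YDL020C, a proteasome gene activator, 0.72 ± 0.10) and IMD2 (0.68 ± 0.20). It rose on 139 and fell on 358 genes, or 335 and 506 with scaled arrays (1200 called in SC, 24 in SM, 279 for the difference). Leaving out WT SM replicate 1 gave 208, WT SM replicate 2 221, bur1as/ctk1Δ SC replicate 1 256 and SC replicate 2 180. Ribosomal protein genes had 85 of 101 lower (100 over the list alone, mean -0.76, camera adjusted p = 8.55e-49, but adjusted p = 0.056 with an estimated correlation; RPL2B -0.95 ± 0.11). The a-cell markers had 3 of 3 lower (mean -0.88, 0.056), Gcn4 targets 11 of 43 (16 over the list alone, mean -0.30, 0.319), glycolysis genes 6 of 17 (mean -0.51, 0.319) and respiration genes 2 of 19 (mean -0.25, 0.0668). Hsf1 chaperones had a mean of 0.19 (1 of 23 called, lower; 0.319). In the joint fit, 26 genes lay higher for Sth1 than for Rpb3 and 9 lower. The a-cell markers lay higher (2 of 3, mean 0.64), which held with an estimated correlation (0.0235). Hsf1 chaperones lay lower (0 of 23 called, mean -0.304, camera adjusted p = 1.47e-07, but adjusted p = 0.0688 with an estimated correlation), and ribosomal protein (mean 0.208, or -0.0198 with scaled arrays) and methionine genes (0.207) higher with camera only (0.673 and 0.53). The count of 35 fell to between 13 (without WT Sth1 SC replicate 2) and 23 (without bur1as/ctk1Δ Rpb3 SC replicate 1) for the arrays that moved it by more than 1.5 times.

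Between bur1as/ctk1Δ and ctk1Δ, limma called 0 genes for Sth1 (98 at an unadjusted p below 0.05) and no list. Rpb3 rose on BUR6 (YER159C, a transcription regulator gene, 0.92 ± 0.19, SE, 3 against 4 arrays, limma adjusted p = 0.0391), PDR5 (YOR153W, 0.84 ± 0.17), RPB2 (YOR151C, a polymerase II subunit gene, 0.66 ± 0.13) and the proteasome genes' activator RPN4 (0.58 ± 0.10), and fell on STR3 (YGL184C, -0.80 ± 0.16) and TAL1 (YLR354C, -0.74 ± 0.16). The 31 higher and 26 lower genes became 1 called gene without ctk1Δ SC replicate 1, and 0 without ctk1Δ SM replicate 1, SM replicate 2 or SC replicate 2 or either bur1as/ctk1Δ SC array. Camera called 10 lists for Rpb3, and 0 with an estimated correlation. Among the 10, Hsf1 chaperones (mean 0.31) and ribosome biogenesis genes (0.16) were higher and ribosomal protein genes (-0.16) lower, with adjusted p = 0.193, 0.229 and 0.453 with an estimated correlation.

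On the arrays labelled kin28as/bur2Δ, ADE2 (YOR128C) and its neighbour AFI1 topped the Sth1 changes (3.85 ± 0.14 and 0.34 ± 0.07). ADE2 input DNA is missing there, so its value rests on signals near background, and no cause was tested for AFI1. Sth1 fell on the alpha-factor receptor gene STE2 (-0.95 ± 0.13, SE, 4 against 4 arrays, limma adjusted p = 0.00727), the proton pump gene PMA1 (YGL008C, -0.90 ± 0.13), VMA1 (-0.65 ± 0.11), YRA1 (-0.64 ± 0.10) and CDC19 (-0.58 ± 0.09). Sth1 rose on 2 and fell on 15 genes. SC alone called 64 genes, the difference between media 33, and SM alone 5, among them ADE2 (4.36), YDL012C (0.74), ARG56 (-0.59) and HIS4 (-0.82), the last 3 chosen after their values were seen. With the label dyes of the 2 SM arrays the count was 2676. Without 1 array it was 1 (WT SM replicate 1, kin28as/bur2Δ SM replicate 2 or SC replicate 1), 3 (SM replicate 1), 4 (WT SC replicate 1), 5 (SC replicate 2) or 8 (WT SM replicate 2). Ribosomal protein genes had 2 of 101 lower (23 over the list alone, mean -0.20, camera adjusted p = 3.27e-14, but adjusted p = 0.357 with an estimated correlation; RPL17B -0.47 ± 0.07). Gcn4 targets had 1 of 43 lower (18 over the list alone, mean -0.20, 0.249), glycolysis genes 2 of 17 (7 over the list alone, mean -0.25, 0.249) and a-cell markers 1 of 3 (mean -0.45, 0.0861). Purine genes had a mean of 0.16, a median of -0.05 and a camera direction of down.

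Rpb3 on these arrays rose on CIT2 (YCR005C, peroxisomal citrate synthase) by 1.79 ± 0.15 (SE, 4 against 4 arrays, adjusted p = 3.41e-06), HSP26 by 1.07 ± 0.13 and the alpha-cell gene STE3 (YKL178C) by 1.06 ± 0.10. It fell on STE2 (-2.70 ± 0.14, adjusted p = 5.92e-09), BAR1 (-2.03 ± 0.13), STE6 (YKL209C, -1.66 ± 0.10), PMA1 (-1.63 ± 0.23) and ASC1 (-1.33 ± 0.13). It rose on 185 and fell on 368 genes (950 called in SC on different slides, 78 in SM on a shared slide, 139 for the difference). The count was 231, 271 and 277 without WT SM replicate 1, WT SM replicate 2 and WT SC replicate 1, and 288, 189, 344 and 1925 without kin28as/bur2Δ SM replicates 1 and 2 and SC replicates 1 and 2. The a-cell markers fell, 3 of 3, by -2.13 on average, which held with an estimated correlation (0.00529). Ribosomal protein genes had 31 of 101 lower (48 over the list alone, mean -0.32, camera adjusted p = 1.51e-11, but adjusted p = 0.367 with an estimated correlation), Gcn4 targets 11 lower and 1 higher of 43 (mean -0.28, 0.378; HIS1 -0.70 ± 0.09), glycolysis genes 8 of 17 lower (mean -0.40, 0.367) and Hsf1 chaperones 5 of 23 higher (mean 0.22, 0.331; CPR6 0.78 ± 0.09). In the joint fit the Sth1 change lay above the Rpb3 change on 53 genes and below it on 22, and 3 of 3 a-cell markers lay above (mean 1.68, 1.25e-05 with an estimated correlation). Hsf1 chaperones lay below (3 of 23, 5 over the list alone, mean -0.32), which held too (0.0467). Ribosomal protein (mean 0.124, or -0.0456 with scaled arrays) and purine genes (0.228) lay above with camera only (0.793 and 0.168). With the label dyes 1370 genes were called. Without kin28as/bur2Δ Rpb3 SC replicate 2 the joint count was 660, and the other arrays that moved it by more than 1.5 times gave 27 (without kin28as/bur2Δ Rpb3 SM replicate 2) to 47 (without Sth1 SM replicate 2).

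**Figure D2:**
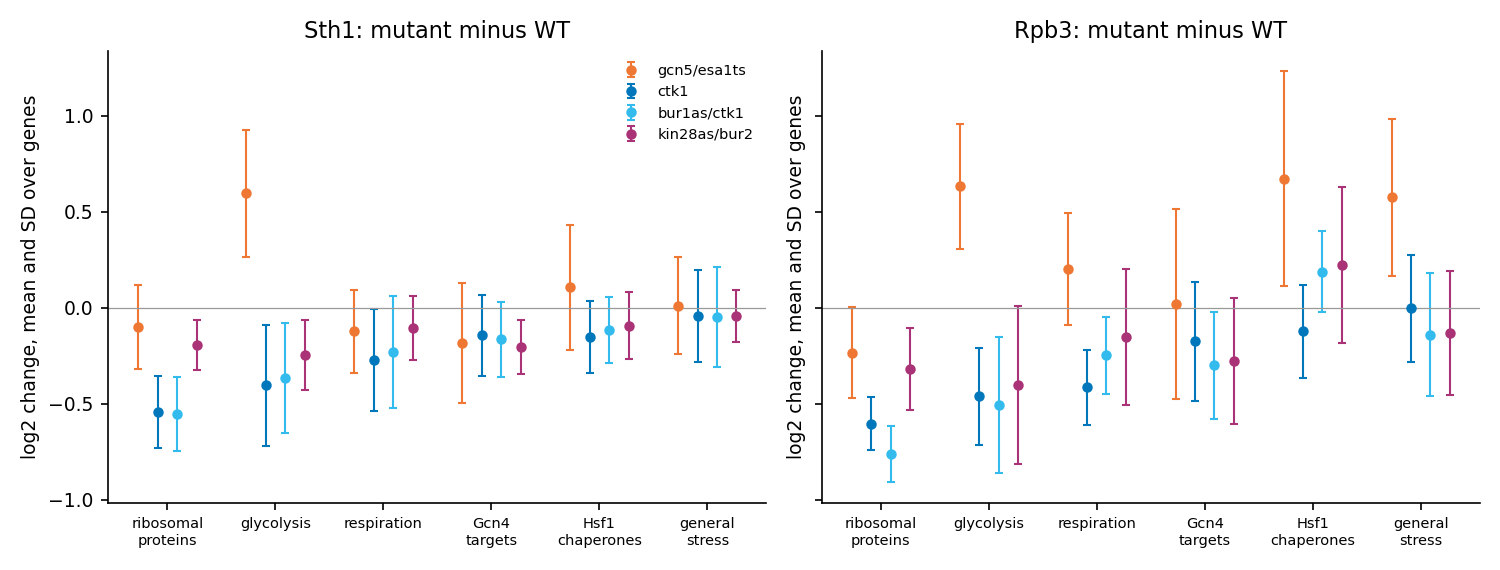
Mean log2 change from WT over the genes of 6 lists for Sth1 (left) and Rpb3 (right) in 4 mutants, where points are list means and bars the SD over genes, not over arrays. Sth1 on ribosomal protein genes lies at -0.54 in ctk1Δ and -0.56 in bur1as/ctk1Δ, and at -0.10 in gcn5Δ/esa1ts (0.02 with scaled arrays).

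Values per array, which need no model across genes, were compared with WT. Sth1 on the 200 genes of highest Rpb3, relative to other genes, was 0.95 ± 0.29 in WT (SD, n = 4). It was 0.43 ± 0.19 in ctk1Δ (difference -0.52, exact two-sided p = 0.0286, adjusted p = 0.114), with -0.90 in SC and -0.14 in SM. In bur1as/ctk1Δ it was 0.42 ± 0.21 (n = 3, difference -0.53, exact p = 0.0857, adjusted p = 0.171). In gcn5Δ/esa1ts it was 0.83 ± 0.14 (exact p = 0.543) and in kin28as/bur2Δ 0.83 ± 0.13 (exact p = 0.514). Rpb3 on these genes differed from the WT value of 1.58 ± 0.49 by 0.07, -0.40, -0.66 and -0.18 in gcn5Δ/esa1ts, ctk1Δ, bur1as/ctk1Δ and kin28as/bur2Δ (exact p = 0.829, 0.2, 0.0857 and 0.571). The first of these was negative without WT SM replicate 1 (-0.07), WT SM replicate 2 (-0.04) or gcn5Δ/esa1ts SC replicate 2 (-0.05). Without WT SC replicate 2 the differences were 0.29, -0.178, -0.438 and 0.0454 in the same order.

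Sth1 over tRNA intervals was 0.14 ± 0.05 in ctk1Δ (SD, n = 4, difference -0.32) and 0.07 ± 0.07 in bur1as/ctk1Δ (n = 3, difference -0.39), both with an exact two-sided p of 0.0286 and an adjusted p of 0.0571. It was 0.68 ± 0.14 in gcn5Δ/esa1ts (difference 0.21, exact p = 0.0857). In kin28as/bur2Δ it was 0.45 ± 0.05 (difference -0.02, exact p = 0.943), and the difference was 0.06 without WT SC replicate 2 and 0.00 without kin28as/bur2Δ SM replicate 1. Upstream minus CDS Sth1 was 0.22 ± 0.10 in WT, -0.04 ± 0.03 in both ctk1Δ and bur1as/ctk1Δ (exact p = 0.0286, adjusted p = 0.0571 for each), 0.38 ± 0.07 in gcn5Δ/esa1ts (exact p = 0.0571) and 0.21 ± 0.03 in kin28as/bur2Δ (exact p = 0.886). That last difference of -0.01 turned positive without either WT SC array or kin28as/bur2Δ SC replicate 2 (0.01 to 0.04). With the label dyes of the kin28as/bur2Δ SM arrays the differences of Sth1 in that strain were -0.87 on the 200 highest genes, -0.44 over tRNA intervals and -0.24 for upstream minus CDS. Rpb3 in the last minus the first of 3 equal parts of long, highly transcribed genes differed from WT by 0.17 in ctk1Δ (exact p = 0.0286, adjusted p = 0.114, and 0.105 without WT SC replicate 1) and by -0.33 in kin28as/bur2Δ (exact p = 0.0571, adjusted p = 0.114). The other values of this kind, for Rpb3 and Sth1, had exact p of at least 0.0857. No adjusted p was below 0.05, and 3 against 4 arrays cannot give an exact p below 0.0286. These tests treat media, and arrays that share a slide, as exchangeable. The bur1as/ctk1Δ arms are unbalanced over SC and SM, so their differences mix medium with strain.

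**Figure D3:**
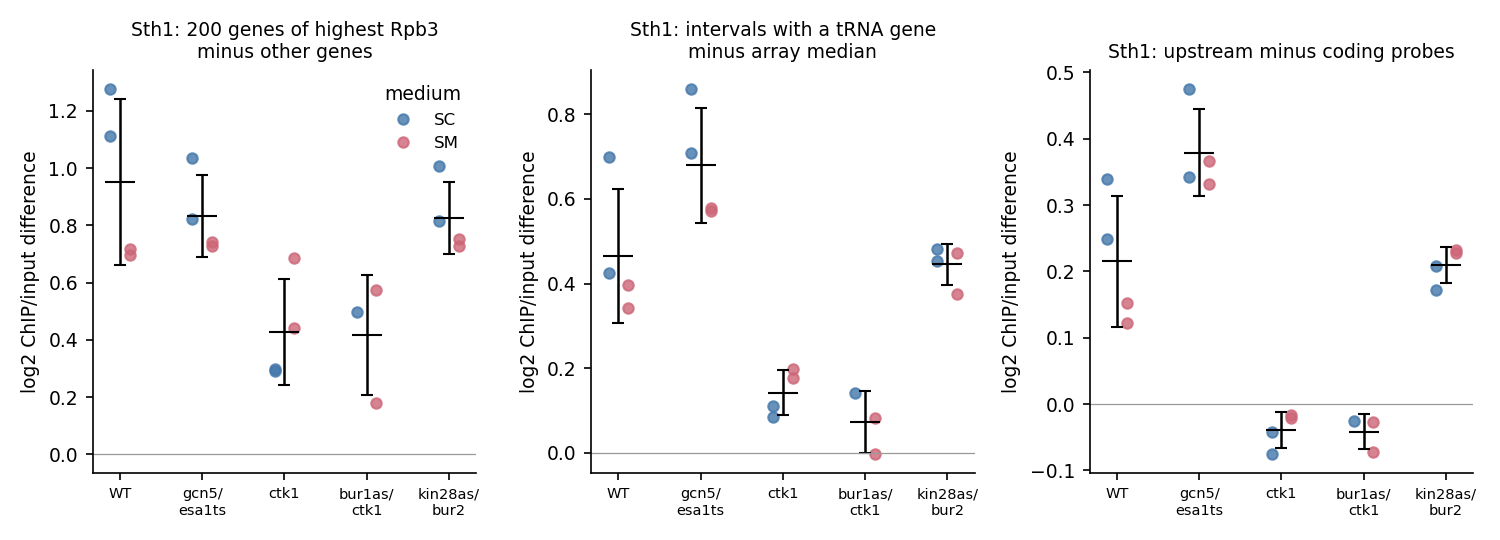
Each point is 1 Sth1 array in SC or SM, with the strain's mean and SD, for log2 ChIP/input on the 200 genes of highest Rpb3 minus other genes (left), tRNA intervals minus the array median (middle) and upstream minus coding probes (right). Upstream minus coding values are -0.04 ± 0.03 in ctk1Δ and bur1as/ctk1Δ and 0.22 ± 0.10 in WT.

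Doxycycline was added to STH1-TET to ask how repression of STH1 affects polymerase II and H3. Without doxycycline Rpb3 on STH1 lay above WT, so the comparison sets repressed against raised STH1 transcription, not loss against the WT level. Sth1 itself was not measured in this strain. Rpb3 rose on LDO16 (YMR148W, 1.12 ± 0.28, SE, 3 doxycycline against 4 other arrays, limma adjusted p = 0.0297), PXR1 (YGR280C, 1.07 ± 0.20) and the peptide transporter gene PTR2 (YKR093W, 1.04 ± 0.20). It fell on CDC123 (YLR215C, -1.44 ± 0.42, adjusted p = 0.0442), RTT102 (YGR275W, itself an RSC subunit gene, -1.38 ± 0.39) and IMO32 (YGR031W, -1.37 ± 0.26). RTT102 was -0.876 without doxycycline SC replicate 2, -0.935 without untreated SM replicate 2, -1.42 and -1.33 without untreated SC replicates 1 and 2 (not called in these 4 settings), and -1.97 without doxycycline SC replicate 1. Rpb3 rose on 167 and fell on 355 genes, or 552 and 651 in the value table. Each medium alone called 1 gene, YEL1 (YBL060W, -0.83, adjusted p = 0.0245) in SC and BSC5 (YNR069C, -1.30, adjusted p = 0.0478) in SM, named after their values were seen, and limma called 0 for the difference (193 at an unadjusted p below 0.05). The count of 522 was 0 without SM replicate 2 or SC replicate 2 of the untreated arrays, 1 without doxycycline SC replicate 2, 169 and 1269 without untreated SC or SM replicate 1, 2428 without doxycycline SC replicate 1, and 2825 with the label dyes of the turned SM array. Of the lists only the a-cell markers were called (2 of 3 lower, 3 over the list alone, mean -0.58, camera adjusted p = 0.0473, but adjusted p = 0.455 with an estimated correlation). The Gcn4 response to SM was 1.93 without doxycycline (42 genes higher) and 1.96 with it (38). Its change was -0.03 as a list mean and 0.03 against other genes (adjusted p = 0.973), so its sign is not settled. That last value was -0.19 and 0.28 without untreated SM replicates 1 and 2, -0.04 without untreated SC replicate 1 and -0.14 without doxycycline SC replicate 2. With the label dyes the response with doxycycline was -2.19.

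H3 with and without doxycycline was measured in SC on a shared slide. Over coding sequences limma called 0 genes (1409 at an unadjusted p below 0.05). The number of called genes rose from 0 to 588 without replicate 1 of either group and 1 without replicate 2 of either. No gene of the ribosomal protein list was called (33 lower over the list alone, mean -0.18, camera adjusted p = 5.07e-13, but adjusted p = 0.876 with an estimated correlation). Over upstream probes H3 rose on 667 and fell on 466 of 5167 genes, but the count was 17 without untreated replicate 2, 0 without doxycycline replicate 2, and 0 without the dye term, with scaled arrays or in the value table. Leading upstream genes were ADH7 (YCR105W, 0.75 ± 0.07, SE, 2 against 2 arrays, adjusted p = 0.00452), MKK2 (YPL140C, 0.72 ± 0.07), LPX1 (YOR084W, -1.13 ± 0.17) and RPL13B (YMR142C, -0.69 ± 0.13, but 0.03 with normexp background and -0.353 without untreated replicate 2). The upstream ribosomal protein list had 29 of 125 lower (30 over the list alone, mean -0.16, 0.781 with an estimated correlation; RPL34A -0.54 ± 0.09, or -0.358 without untreated replicate 2), and meiosis genes 11 higher and 1 lower of 35 (mean 0.12, 0.781).

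Across 5 equal bins of genes in rising order of WT SC Sth1, the mean H3 change over CDS went from 0.08 to -0.16 and the mean Rpb3 change from 0.40 to -0.34. With ChIP in green H3 went from 0.03 to -0.07 and Rpb3 from 0.07 to -0.09. In red they went more steeply, from 0.12 to -0.24 and 0.72 to -0.60. The red doxycycline Rpb3 array had a narrower spread (SD 0.775 against 1.016 untreated), whose effect here was not tested. The H3 and Rpb3 changes correlated across genes (r = 0.569, rho = 0.547, 4976 genes, which are not independent replicates), and r between opposite dyes was 0.205 and 0.419. The r was -0.46 without H3 doxycycline replicate 2, -0.03 without untreated H3 replicate 1 and 0.39 without Rpb3 doxycycline SC replicate 2, so the relation rests on single arrays.

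**Figure D4:**
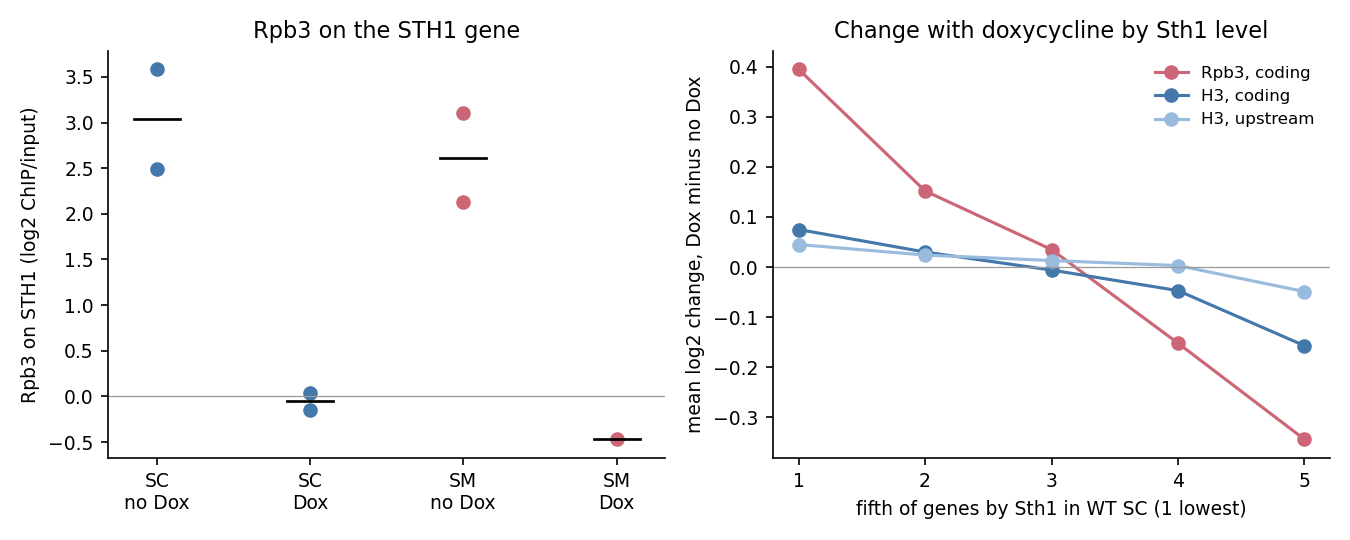
Left, Rpb3 log2 ChIP/input on the STH1 gene for each STH1-TET array, with group means as bars. Right, mean log2 change with doxycycline in SC for 5 equal bins of genes by WT SC Sth1. Points are means over genes and both dyes, and Rpb3 goes from 0.40 to -0.34 and H3 over CDS from 0.08 to -0.16.

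Without doxycycline, STH1-TET in SM was compared with SC as a second look at the response to SM. Rpb3 rose on ARG1 by 4.25 ± 0.34 (SE, 2 against 2 arrays, limma adjusted p = 3.83e-07), HIS4 by 3.57 ± 0.20 and ADH5 (YBR145W) by 3.53 ± 0.33. It fell on the chaperone gene HSC82 (YMR186W, -2.06 ± 0.19), UTP5 (YDR398W, -1.89 ± 0.19), NHP2 (YDL208W, -1.85 ± 0.29) and DBP2 (YNL112W, -1.78 ± 0.23), the last 3 of which act in ribosome assembly. It rose on 908 and fell on 511 genes, and the median of all genes was 0.13. The count of 1419 was 808 without SC replicate 1 and 721 without SC replicate 2. With an estimated correlation 4 lists held. Gcn4 targets rose (42 of 43, mean 2.08, adjusted p = 0.0256; HIS5 3.06 ± 0.15), as did stress genes (22 of 24, mean 1.24, 0.0468; PNC1 1.79 ± 0.20) and purine genes (9 of 15, mean 0.74, 0.0442; GCV1 1.22), and ribosome biogenesis genes fell (40 of 53, mean -0.82, 0.00646). Hsf1 chaperones (11 lower, 2 higher of 23, mean -0.37, 0.27), methionine genes (9 higher, 2 lower of 19, mean 0.63, 0.27) and a-cell markers (3 of 3 higher, mean 1.34, 0.0719) did not hold.

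H3 in SM against SC without doxycycline gave 1495 higher and 1960 lower genes, with GPI14 (YJR013W) at 1.87 ± 0.07 (SE, 2 against 2 arrays, limma adjusted p = 8.51e-05) and PET122 (-2.40 ± 0.30), WHI5 (-2.20 ± 0.14) and RSO55 (-2.06) lowest. The 2 SM arrays came from another scanner, their input channel was saturated at 13.8% and 14.5% of spots, and limma without a dye term called 0 genes. The Gcn4 targets (40 of 43 lower, mean -0.54) and ribosomal protein genes (85 lower and 1 higher of 101, mean -0.61) were called with camera but not with an estimated correlation (0.883 for both).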

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

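The tests chosen only after the result was seen are those of WT arrays that stand apart, of polymerase number, of lost DNA, of mating type and of a signal with any antibody.

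The change from WT differed between SM and SC by limma's test of the difference itself. For Sth1 this held for 137 genes in gcn5Δ/esa1ts, 995 in ctk1Δ, 9 in bur1as/ctk1Δ and 33 in kin28as/bur2Δ. For Rpb3 it held for 585, 215, 279 and 139 genes in the same order. The Gcn4 targets were among the genes whose response to SM was smaller than in WT by camera, with mean differences for Rpb3 of -0.628 in gcn5Δ/esa1ts, -0.669 in ctk1Δ, -0.76 in bur1as/ctk1Δ and -0.552 in kin28as/bur2Δ. For Sth1 they were -0.257, -0.35, -0.479 and -0.202. None of these 8 passed with an estimated correlation, all share the WT arrays, and SM and SC arrays lie on different slides, so medium and slide cannot be told apart.

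The input DNA, which the comparisons do not use as a result, showed signals that the strain names do not give. The array labelled bur1as/ctk1Δ Sth1 SC replicate 2 carried CTK1 (0.56, where the other 5 arrays of the strain were below -3) and a high URA3 signal (6.60). The arrays labelled kin28as/bur2Δ carried BUR2 (median -0.06), lacked ADE2 (-6.09), LYS2 (-5.81) and TRP1 (-3.61) and had high URA3 (6.73), a level otherwise seen on STH1-TET arrays (median 7). A mislabelled sample or another strain background could each give such values. Other causes were not examined, and the files do not decide between them. Results of the bur1as/ctk1Δ Sth1 SC array therefore may not describe cells without CTK1. Without it the Sth1 comparison of that strain rests on its 2 SM arrays, which called 818 genes.

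Sth1 was lower on the 200 most transcribed genes on the 7 ctk1Δ and bur1as/ctk1Δ arrays than on the 4 WT arrays, by -0.53 (exact two-sided p = 0.00303 over 330 splits). For each strain alone the exact test did not pass after adjustment (adjusted p = 0.114 in ctk1Δ and 0.171 in bur1as/ctk1Δ). Both strains differed more in SC (-0.90 and -0.70) than in SM (-0.14 and -0.33). A narrower spread of log ratios on those arrays was argued against by a difference of -0.351 with every array at one spread. WT arrays that stand apart were argued against by -0.434 against the 6 gcn5Δ/esa1ts and kin28as/bur2Δ arrays of undisputed direction. It was -0.405 with the 2 turned arrays as used and -0.0349 with their label dyes. Fewer polymerases on these genes is a candidate explanation, looked at on the ribosomal protein list. Rpb3 fell on that list too with camera (but adjusted p = 0.118 in ctk1Δ and 0.056 in bur1as/ctk1Δ with an estimated correlation). The Sth1 change minus the Rpb3 change of the list was 0.135 on average over both strains. That value was 0.06 in ctk1Δ (adjusted p = 0.389) and 0.21 in bur1as/ctk1Δ (adjusted p = 5.72e-06, but adjusted p = 0.673 with an estimated correlation), both -0.02 with scaled arrays, so on this list Sth1 was not found to fall more than Rpb3 in log2. On the 200 genes the differences from WT for Sth1 and Rpb3 were -0.52 and -0.40 in ctk1Δ, and -0.53 and -0.66 in bur1as/ctk1Δ. In WT these genes stood at 0.95 for Sth1 and 1.58 for Rpb3, so equal log2 falls are unequal shares of each signal. The values therefore do not decide whether Sth1 fell only with the polymerase. A loss of RSC recruitment by the kinase itself was not tested apart from transcription, and strain cannot be told apart from slide or scan day. The 7 arrays were scanned on days 5 and 7, on which no WT, gcn5Δ/esa1ts or kin28as/bur2Δ Sth1 array was scanned. The array among them that carries CTK1 was low too, at 0.50 against 0.95 in WT, so lack of CTK1 is not shown to be common to the low arrays.

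Rpb3 on the a-cell genes STE2, BAR1, STE6 and AGA2 was lower on the arrays labelled kin28as/bur2Δ than in WT, by -1.98 (exact two-sided p = 0.0286, 4 against 4 arrays). Loss of their DNA was argued against, since their input signal averaged 0.189. Another mating type in that strain is a candidate explanation, since Rpb3 on 4 alpha-cell genes was higher by 1.29 (exact p = 0.0286). That mean rests on MF(ALPHA)1 (1 probe, -1.21 in WT and 2.43 on these arrays) and STE3 (-1.18 and 0.02), while SAG1 (-0.54 and -0.25) and MF(ALPHA)2 (0.26 and 0.43) moved less, where these WT values include YPD. An effect of the kinases on these genes was not tested separately.

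Sth1 was lower on PET122, RRN5, RSO55, WHI5, PHO4, YAT1 and SCS3 on the ctk1Δ and bur1as/ctk1Δ arrays than on WT arrays, by -1.82. This restates their choice as large decreases and is no test. These genes stood at a median percentile of 99.8 among all genes for WT SC Sth1, 90.9 for WT SC Rpb3, and 32.4 in SC and 0.322 in SM for H3 without doxycycline. WT arrays that stand apart were argued against for the genes as a mean, by the same 6 arrays of undisputed direction. The 8 genes chosen in ctk1Δ differed by -1.32 on the bur1as/ctk1Δ arrays (exact p = 0.0119, or -0.465 with the turned arrays in their label dyes). The 8 chosen in bur1as/ctk1Δ differed by -1.16 on the ctk1Δ arrays (exact p = 0.0143, or -0.262 with the label dyes). PET122 is an exception, since its Sth1 fell about as much in gcn5Δ/esa1ts. Strain and scan day cannot be told apart here either, and weaker Sth1 enrichment on the ctk1Δ and bur1as/ctk1Δ arrays is not excluded. A signal of the PHO4 probes with any antibody was argued against too, since H3 on PHO4 reached at most percentile 2.49 on the 6 H3 arrays (SD 0.974). For the other 6 genes such a signal cannot be told apart from Sth1 binding, because in SC their H3 percentiles ranged from 11.5 to 99.9 and differed between dyes (RRN5 at 89.2 and 0.221). The low SM values (all 7 at 12.2 or less) come from 2 arrays with the same dye, another scanner and saturated input, and the bound for the 7 genes was changed after the value was seen to ask for a common level.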

How the results depend on the processing

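Tests chosen only after the data were seen are those with the label dyes, without the 3 turned arrays, without the array carrying CTK1, with 500 genes for the profile along genes, and with gcn5Δ/esa1ts and kin28as/bur2Δ arrays as the control, in each of 3 forms. Where no cause is named below, the cause was not tested. Of the results that answer a comparison, 611 of the recomputed values kept their direction and side of the threshold, 85 counts moved by more than 1.5 times, 18 values no longer passed, 14 came to pass and 15 changed sign. For single named genes and side values these numbers were 1703 kept, 202 no longer passing, 3 now passing and 8 with a changed sign. Bright probes alone, 100 or 500 highest genes and a 250 bp upstream window changed none of the results they were applied to. Slide as a block was fitted only where all groups of a comparison lie on 1 slide (YPD against SC for both antibodies, H3 with doxycycline), and it cannot move these 4 counts because no group spans slides.

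The count for Rpb3 in SM against SC ranged from 977 to 1447 over the alternatives other than leaving out an array, that for Sth1 in ctk1Δ from 1016 to 1859 and that for STH1-TET Rpb3 in SM from 1074 to 1863. The Rpb3 response of Gcn4 targets in WT lay between 1.59 and 2.21, and that of Sth1 between 0.56 and 0.77, in every alternative and without any 1 array.

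With normexp background correction the number of called genes went from 46 to 27 for Rpb3 in YPD, from 578 to 277 for Sth1 in SM, from 0 to 4 for Sth1 in YPD, from 1488 to 982 for Sth1 in gcn5Δ/esa1ts, from 895 to 459 for Sth1 in bur1as/ctk1Δ and from 17 to 9 for Sth1 in kin28as/bur2Δ. For Rpb3 it went from 598 to 323 in ctk1Δ, 497 to 217 in bur1as/ctk1Δ, 553 to 302 in kin28as/bur2Δ and 522 to 246 with doxycycline. For H3 with doxycycline it went from 0 to 243 over coding sequences and from 1133 to 209 upstream. Joint fits went from 512 to 330 in gcn5Δ/esa1ts, 35 to 8 in bur1as/ctk1Δ and 75 to 28 in kin28as/bur2Δ. The Sth1 response of Gcn4 targets in bur1as/ctk1Δ (0.0878) no longer passed. The change of that Rpb3 response with doxycycline turned to -0.18, the Rpb3 profile along genes to 0.024 in gcn5Δ/esa1ts and -0.0541 with doxycycline, and H3 upstream of RPL13B from -0.69 to 0.0276.

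Scaling arrays to one spread gave 16 genes for Rpb3 in YPD, 223 for Sth1 in SM, 841 for Rpb3 in bur1as/ctk1Δ, 591 for Rpb3 in bur1as/ctk1Δ against ctk1Δ, 253 for Rpb3 with doxycycline and 0 for H3 upstream. Its joint fits gave 86 in ctk1Δ, 255 in bur1as/ctk1Δ and 122 in kin28as/bur2Δ. The doxycycline change of the Gcn4 response came to pass (0.35), and the tRNA differences of Sth1 did so in gcn5Δ/esa1ts (0.30), ctk1Δ (-0.25) and bur1as/ctk1Δ (-0.35). Sth1 on the 200 highest genes in gcn5Δ/esa1ts turned to 0.0282, the Rpb3 profile with doxycycline to -0.00244 and upstream minus CDS Sth1 in kin28as/bur2Δ to 0.00722.

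Without the dye term fewer genes were called, with 16 for Rpb3 in YPD, 158 for Sth1 in SM, 947 for Sth1 in gcn5Δ/esa1ts, 519 in bur1as/ctk1Δ and 2 in kin28as/bur2Δ. Rpb3 gave 255 in ctk1Δ, 199 in bur1as/ctk1Δ, 251 in kin28as/bur2Δ, 0 for bur1as/ctk1Δ against ctk1Δ and 268 with doxycycline. H3 gave 0 upstream with doxycycline and 0 in SM against SC. Joint fits gave 233 in gcn5Δ/esa1ts, 3 in ctk1Δ, 0 in bur1as/ctk1Δ and 18 in kin28as/bur2Δ.

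With the median of probes the counts were 14 for Rpb3 in YPD, 498 for Sth1 in bur1as/ctk1Δ and 3 in kin28as/bur2Δ, and for Rpb3 357 in ctk1Δ, 281 in bur1as/ctk1Δ, 342 in kin28as/bur2Δ and 0 for bur1as/ctk1Δ against ctk1Δ. Joint fits gave 336 in gcn5Δ/esa1ts, 2 in ctk1Δ, 2 in bur1as/ctk1Δ and 18 in kin28as/bur2Δ. The Sth1 response of Gcn4 targets in bur1as/ctk1Δ (0.0479) no longer passed, and the Rpb3 profile with doxycycline turned to -0.0685. With at least 1 CDS probe, Sth1 in YPD had 22 genes and H3 with doxycycline 1.

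A fit on only the arrays of the groups compared, which leaves fewer degrees of freedom, gave 0 genes for Rpb3 in YPD, 1538 for Sth1 in SM, 12 for Sth1 in bur1as/ctk1Δ and 43 in kin28as/bur2Δ. Rpb3 gave 2260 in gcn5Δ/esa1ts, 1162 in ctk1Δ, 218 in bur1as/ctk1Δ, 5 in kin28as/bur2Δ, 1738 for bur1as/ctk1Δ against ctk1Δ and 0 with doxycycline, and H3 over coding sequences 463. Joint fits gave 1467 in gcn5Δ/esa1ts, 33 in ctk1Δ, 0 in bur1as/ctk1Δ and 5 in kin28as/bur2Δ.

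The value table, which holds 3 more arrays, gave 26 genes for Rpb3 in YPD, 5 for Sth1 in YPD, 1733 for Sth1 in bur1as/ctk1Δ, 1007 for Rpb3 in bur1as/ctk1Δ, 86 for Rpb3 in bur1as/ctk1Δ against ctk1Δ, 1203 for Rpb3 with doxycycline and 0 for H3 upstream. Its joint fits gave 16 in ctk1Δ, 73 in bur1as/ctk1Δ and 44 in kin28as/bur2Δ. The Sth1 response of Gcn4 targets in bur1as/ctk1Δ turned to -0.051, and the doxycycline change of the Rpb3 response came to pass (0.55). Rpb3 on the 200 highest genes in gcn5Δ/esa1ts turned to -0.19, tRNA Sth1 in kin28as/bur2Δ to 0.00887, upstream minus CDS Sth1 there to 0.00786 and the Rpb3 profile with doxycycline to -0.0297.

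With the label dyes for the 3 turned arrays, 2676 genes were called for Sth1 in kin28as/bur2Δ, 2825 for Rpb3 with doxycycline and 1370 in the joint fit of kin28as/bur2Δ. The Gcn4 response turned to -0.43 for Sth1 in kin28as/bur2Δ and -2.19 for Rpb3 with doxycycline, whose change turned to -4.12, and the Sth1 profile in kin28as/bur2Δ to 0.12. The Sth1 difference of that response in kin28as/bur2Δ went from -0.271 to -1.03, the Rpb3 profile with doxycycline from 0.00591 to 0.173, and called lists from 5 to 8 for Sth1 in kin28as/bur2Δ, from 1 to 10 for Rpb3 with doxycycline and from 95 to 107 in all. ADE2 went from 3.85 to -0.45 over both media and from 4.36 to -4.24 in SM, YDL012C in SM from 0.74 to -0.25, and PTR2 with doxycycline from 1.04 to -0.72. Without these arrays tRNA Sth1 in kin28as/bur2Δ turned to 0.00181, and the Rpb3 drop on STH1 (-2.88) no longer passed, with 2 doxycycline arrays left. With gcn5Δ/esa1ts and kin28as/bur2Δ as the control, Sth1 on the 200 highest genes came to pass in ctk1Δ (-0.40) and bur1as/ctk1Δ (-0.41), as did tRNA Sth1 (-0.42 and -0.49). Without the 2 turned arrays in that control these values were -0.429, -0.441, -0.466 and -0.536 and passed too. With their label dyes they were -0.0297, -0.0419, -0.208 and -0.278 and did not pass.

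The replicate number as a block in place of the dye term is close to the dye itself. Replicate 1 carries ChIP in green in all 10 Sth1, 13 Rpb3 and 3 H3 groups with 2 arrays, but so does replicate 2 of STH1-TET H3 SM, and the 1 STH1-TET Rpb3 SM doxycycline array, replicate 1, carries it in red as used here. The numbers are not shown to pair the arrays, since differences of replicates correlated above 0.1 in 35 of 45, 64 of 78 and 2 of 3 pairs of groups. The block gave 1331 genes for Rpb3 with doxycycline, 0 for H3 upstream, 744 for H3 in SM and a doxycycline change of the Gcn4 response of 0.15, which came to pass.

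With an estimated correlation, camera called 13 list tests in place of 95. The Gcn4 responses of Sth1 in gcn5Δ/esa1ts (0.28), ctk1Δ (0.21), bur1as/ctk1Δ (0.0799) and kin28as/bur2Δ (0.33) no longer passed. Neither did the differences from WT against other genes, for Rpb3 -0.61, -0.67, -0.81 and -0.60 and for Sth1 -0.32, -0.39, -0.52 and -0.27 in gcn5Δ/esa1ts, ctk1Δ, bur1as/ctk1Δ and kin28as/bur2Δ. With fry the Sth1 response in bur1as/ctk1Δ (0.0762) and its differences in gcn5Δ/esa1ts (-0.26) and kin28as/bur2Δ (-0.20) did not pass, and the doxycycline change, as a list mean, was -0.0329.

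Leaving out 1 array, which leaves some groups with a lone array assumed to vary like the others, gave counts of 662 to 1034 for Rpb3 in SM, 3 to 231 for Rpb3 in YPD, 42 to 208 for Sth1 in SM and 0 to 888 for Sth1 in YPD. Sth1 counts were 866 to 1293 in gcn5Δ/esa1ts, 698 to 1236 in ctk1Δ, 435 to 850 in bur1as/ctk1Δ and 1 to 18 in kin28as/bur2Δ. Rpb3 counts were 582 to 1204 in gcn5Δ/esa1ts, 186 to 643 in ctk1Δ, 180 to 492 in bur1as/ctk1Δ, 189 to 1925 in kin28as/bur2Δ, 0 to 1 for bur1as/ctk1Δ against ctk1Δ, 0 to 2428 with doxycycline and 721 to 1255 for STH1-TET in SM. H3 with doxycycline gave 1 to 588 over coding sequences and 0 to 934 upstream. Joint fits gave 246 to 622 in gcn5Δ/esa1ts, 3 to 10 in ctk1Δ, 13 to 46 in bur1as/ctk1Δ and 27 to 660 in kin28as/bur2Δ. The Gcn4 response of Sth1 in bur1as/ctk1Δ ranged from 0.0139 to 0.161 and the doxycycline change from -0.19 to 0.28. Rpb3 on the 200 highest genes ranged from -0.0707 to 0.29 in gcn5Δ/esa1ts and -0.315 to 0.0454 in kin28as/bur2Δ, where tRNA Sth1 ranged from -0.0611 to 0.0574 and upstream minus CDS from -0.037 to 0.0357. The Rpb3 profile with doxycycline ranged from -0.062 to 0.0663, the correlation of H3 and Rpb3 changes from -0.46 to 0.72, and the Rpb3 drop on STH1 from -3.25 to -2.77. Of the values for named genes and side results, 863 were kept, 234 no longer passed and 7 changed sign.

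Signal over background limits little in the input, by the counts given above. It does limit genes deleted from a strain, such as ADE2, whose ratios rest on signals near background.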

Other observations

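The tests of other splits of the arrays were chosen before their results were seen, and the mating-type values below were looked at after.

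The a-cell gene STE2 had these values in each strain. Rpb3 on STE2 was 1.85 ± 0.74 (SD, n = 6) in WT, 1.63 ± 0.95 in STH1-TET (n = 7), 1.4 ± 0.48 in ctk1Δ (n = 4), 1.29 ± 0.68 in bur1as/ctk1Δ (n = 3), 0.95 ± 1.19 in gcn5Δ/esa1ts (n = 4) and -0.59 ± 1.22 on the arrays labelled kin28as/bur2Δ (n = 4). Sth1 on STE2 was 0.23 ± 0.45 in WT (n = 6), 0.06 ± 0.05 in ctk1Δ and -0.55 ± 0.44 on the arrays labelled kin28as/bur2Δ. These means pool media and both dyes, and also YPD arrays in WT and 3 doxycycline with 4 untreated arrays in STH1-TET, so they do not compare strains alone.

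Every split of the arrays of a comparison into groups of the same sizes was refitted on those arrays alone, with 33 splits each that kept the model estimable (31 for the bur1as/ctk1Δ joint fit). The real split then called fewer genes than the fit to all arrays, except for Sth1 in bur1as/ctk1Δ against ctk1Δ, with 0 in both. No other split called as many genes for Sth1 in gcn5Δ/esa1ts (557 genes, highest other split 1), ctk1Δ (460, highest other 7) and bur1as/ctk1Δ (127, highest other 62). For Rpb3 no other split called any gene in gcn5Δ/esa1ts (575 in the real split), ctk1Δ (284) and kin28as/bur2Δ (6). Nor did any for the joint fits of gcn5Δ/esa1ts (330) and kin28as/bur2Δ (5). The share of 1 in 33 is the lowest possible and was not adjusted over the comparisons. The splits treat arrays as exchangeable, while the arrays of a group share a slide, so a slide effect could give the same outcome. Chance is therefore argued against for each comparison singly, in these split fits only, and slide effects are not.

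Chance cannot be excluded for Sth1 in kin28as/bur2Δ, where the real split called 5 genes and 2 of 33 splits called as many. The highest other split called 17 and set kin28as/bur2Δ SM with WT SC against the rest, so both arms held both media and it followed the difference of the strains between media. For Sth1 in bur1as/ctk1Δ against ctk1Δ the real split called 0 and another 1205, which points to a structure of the samples, since its arm of both ctk1Δ SC arrays and a bur1as/ctk1Δ SM array parts arrays within strains. For Rpb3 with doxycycline the real split called 0 and another 2498, which points to a structure of the samples within the treatment groups, its arm holding arrays of both treatments. The real split also called 0 for Rpb3 in bur1as/ctk1Δ against WT and against ctk1Δ (highest other 1 in both). It did so too for the joint fits of ctk1Δ and bur1as/ctk1Δ (highest other 0). Where the real count is 0 every split calls as many whatever the data, so in these 6 comparisons chance was not tested and is not excluded.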
